A study of Mus musculus with 15 samples.

How the data were processed

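Jejunal epithelial cells of 15 CC027/GeniUnc mice were profiled by RNA sequencing of polyadenylated RNA with paired reads of 151 bp. Per the labels' protocols, mice received 2 mg of peanut extract or PBS by gavage weekly for 3 weeks and 5 mg of peanut extract or PBS in week 4, and challenged mice later received 12 mg of peanut extract by gavage. A stretch of jejunum of 4 cm that began 6 cm beyond the pylorus was kept for 75 min at room temperature with EDTA (2 mM) and DTT (0.5 mM), and the epithelium was then shaken off. Such isolates can also hold intraepithelial lymphocytes and some cells of the tissue below, so marker lists of other cell types were tested along with the epithelial lists. The shares of crypt cells and villus cells in each isolate were not measured here. Changes within cells are thus not separated from changes in these shares. The labels give each library its group. The titles of the 15 libraries carry different numbers, and the libraries were taken to come from 15 mice. Replicate numbers here only name the libraries and pair nothing. Mice given PBS and then challenged, and sensitized mice given a gavage without peanut, were not analysed here, so time after gavage, handling and time of day, which the labels used here do not give, are not separated from peanut challenge in any comparison of challenged with unchallenged mice.

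For every library, 139058 transcripts are listed in the deposited data. Per the submitters' processing notes, reads were trimmed with cutadapt 1.18 and quantified with Salmon 1.2.1, with mm10 as the genome build; the transcript annotation release is not given in the sources used here. Per the file headers, each table gives the estimated count of reads per transcript, which need not be a whole number, and its TPM, an abundance scaled to a common total, both made by the authors. The other columns of the deposited tables, per the file headers, are the length and the effective length of each transcript in bases. TPM values were not tested, and served only as weights for the mean effective length of a gene in the correction for transcript length. Transcripts were summed to genes with the GENCODE M21 annotation of GRCm38 (mm10): 137334 transcript IDs matched with their version, 137943 when versions were ignored, and 1115 matched no gene. Those unmatched transcripts held 0.37% to 0.6% of the counts of a library and were left out. The sums over 52844 genes were rounded to whole numbers, since edgeR's model is for counts. Salmon divides reads shared by near-identical transcripts among them, so single genes of the α-defensin, globin and inducible HSP70 families are uncertain.

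Total estimated counts ran from 15661513 to 22691349 per library. Of 28797 genes with any count, 14968 were kept by edgeR's filterByExpr with the groups. Library sizes were scaled by TMM, and edgeR 4.0.16 (estimateDisp and glmQLFit, both robust, then glmQLFTest) was run in R 4.3.3 with all 15 libraries in 1 fit with a mean per group and 10 residual degrees of freedom. The common biological coefficient of variation was 0.26. Contrasts were sensitized against PBS mice, each time after challenge against the sensitized controls, the mean of the 3 times against the sensitized controls, the 3 times tested jointly, and each pair of times. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Fold changes carry the standard error from the quasi-likelihood F statistic, and log2 CPM values used a prior count of 2. Other tools were limma 3.58.1, DESeq2 1.42.0, sva 3.50.0 and version 1.17.8 of data.table, with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 for joining tables and drawing.

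The design, the alternatives, the rule for named genes and 40 gene lists were fixed before the data were examined. Named genes are, for each comparison with a control, the 12 largest rises and falls (6 between times) among genes past the threshold with a mean of at least 2 CPM and no overlap between treated and control libraries, without numbered gene models and antigen receptor segments; members of the lists past the threshold, or up to 4 in order of p where none passes; Il33, Mcpt1, Fos and Egr1 always; and, with fewer than 5 genes past, the 10 smallest p as not passing. Some genes that this rule takes are not reported here, and they stay in the counts. Tslp and Il25 were on the list of genes always given and were too low to be tested. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 37 lists with at least 4 tested genes, and again with the correlation estimated from these libraries. With the estimated correlation 0 lists passed in any comparison. The lowest adjusted p were then 0.829, 0.37, 0.555 and 0.115 for sensitization, 30, 60 and 120 min and 0.456 for the average. They were 0.958, 0.106 and 0.0907 for 30 against 60, 60 against 120 and 30 against 120 min. In every list called the median, the mean and the test had the same sign. Among lists not called, these differed in sign in 8, 8, 7 and 2 lists for sensitization, 30, 60 and 120 min and in 3 for the average. Between 30 and 60, 60 and 120, and 30 and 120 min they did so in 10, 3 and 2 lists. Limma's fry was run too. Its PValue asks whether the genes of a list move, on balance, one way, and its PValue.Mixed whether they change in either direction, and neither compares the list with other genes. By the directional one, 2 lists passed at 60 min and 4 at 120 min, 4 in each comparison of 120 min with an earlier time, and 0 in the others. Some lists share genes. In the mast cell list Kit had the highest mean level (27.5 CPM), and in the granulocyte list Ear2 (11.8 CPM).

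The steps were tested on simulated counts drawn from the means and library sizes of these data. For the 120 min comparison with 200 changed genes, 3.5% were recovered at 1.5-fold (14661 genes tested, 1 false call), 62.5% at 2-fold (14616 tested, 1 false) and 88% at 3-fold (14653 tested, 15 false, 7.85% of the calls), and 0 genes were called at 60 min, where none was changed. A raised list was called and 0 random lists were. Each gene was drawn independently here, so this does not show how the list test behaves where genes of a list vary together. Alternatives fixed beforehand were DESeq2 size factors, no filter or a filter at 1 CPM in 3 libraries, an offset for transcript length, removal of mitochondrially encoded, immunoglobulin and globin genes, 1 surrogate variable, each comparison fitted on its groups alone, limma-voom, DESeq2, PBS mice as control, and each library left out in turn. A sex term was not fitted, since the 15 mice had the expression pattern of 1 sex. The immune marker score (mean log2 CPM of T cell, B cell and macrophage lists) as a covariate, the mitochondrially encoded share as a covariate, and leaving out the 3 libraries with over 25% mitochondrially encoded counts were added after seeing the data. Those 3 libraries were PBS replicate 1 (25.45%), sensitized control replicate 3 (26.73%) and 60 min replicate 3 (33.24%). With 3 libraries against 3, an exact permutation test of a single value cannot give a p under 0.1.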

Results

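Gene expression was measured by bulk RNA sequencing in epithelial cells released from the jejunum, the middle part of the small intestine, of mice of the Collaborative Cross strain CC027/GeniUnc. The 15 mice fell into 5 groups of 3. One group received phosphate-buffered saline (PBS) by gavage and was not challenged. A second group was sensitized to peanut by gavage and was not challenged (the sensitized controls). The other 3 groups were sensitized and then challenged with 12 mg of peanut extract by gavage, with tissue taken 30, 60 or 120 min later. Total estimated counts per library were 19396092, 17832915 and 17764608 in the PBS mice and 19553736, 17715532 and 16617941 in the sensitized controls. They were 22691349, 15661513 and 19987027 at 30 min, 15967713, 18307329 and 19551034 at 60 min, and 21146527, 18768703 and 22215649 at 120 min. Of these counts, mitochondrially encoded genes took 13.76% in 120 min replicate 1 to 33.24% in 60 min replicate 3. Immunoglobulin genes took 0.02% to 0.06% in the 120 min libraries and 0.14% to 0.19% in the sensitized controls. After low-count genes were removed, 14968 genes were tested. Levels are in CPM, which are counts scaled to a common library total, given as mean ± SD over 3 mice, and changes are log2 fold changes ± standard error from edgeR with 3 libraries against 3.

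The comparison of sensitized with PBS mice, both unchallenged, asked what sensitization alone changed in the epithelium. Cell cycle genes were lower in sensitized mice in the camera test only. Of the 17 measured members of the proliferation list 16 had negative log2 fold changes, with a list median of −0.27 (camera adjusted p = 0.000119, and 0.829 with an estimated correlation). In it, the mitotic cyclin Ccnb1 was at 15.2 ± 0.677 CPM in sensitized and 21.2 ± 6.43 CPM in PBS mice, and the DNA topoisomerase Top2a at 47.8 ± 5.44 and 71.9 ± 12.0 CPM. The mean log2 CPM of the proliferation list overlapped between the groups, at 4.71 to 5.01 in sensitized and 5 to 5.3 in PBS mice. In fry's directional test the lowest adjusted p of any list for sensitization was 0.965. All 16 members of the list of PPARα target and fatty acid oxidation genes had positive values, with a median of 0.21 (adjusted p = 0.000146; adjusted p = 0.829 with an estimated correlation). Among these, Acadm, an acyl-CoA dehydrogenase of mitochondria, was at 144 ± 9.52 against 125 ± 14.6 CPM. Markers of T cells and intraepithelial lymphocytes had a median of −0.37 (adjusted p = 0.0011; adjusted p = 0.829 with an estimated correlation), and 15 of the 16 were lower. In these lists no single member passed, either over all genes or adjusted over the list alone.

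No gene passed the threshold after sensitization alone in edgeR, where 212 genes had an unadjusted p under 0.05 and about 748 would by chance; DESeq2 called 6 genes and limma-voom 0. The genes with the smallest p, none of which passed (adjusted p = 1), were led by somatostatin (Sst), a hormone of enteroendocrine D cells, at 21.9 ± 2.57 CPM in sensitized and 11.6 ± 3.32 CPM in PBS mice (0.91 ± 0.24). Sst was also the member of the enteroendocrine list that passed when adjusted over the list alone. Next were the spindle protein Tacc3 (−0.65 ± 0.18), the mitotic kinase Melk (−0.74 ± 0.21), the phosphoinositide phosphatase Sacm1l (0.69 ± 0.20), the mitochondrial nucleotidase Nt5m (0.53 ± 0.16) and separase (Espl1, −0.54 ± 0.17). After them came Cyp2c70 (1.43 ± 0.46), Magt1 (−1.49 ± 0.47) and the kinetochore gene Ndc80 (−0.68 ± 0.22). Klrb1b, a lectin-like receptor of lymphocytes, was at 0.505 ± 0.419 against 0.0172 ± 0.0298 CPM. The epithelial alarmin Il33 (0.16 ± 0.45), the mucosal mast cell protease Mcpt1 (−0.14 ± 0.71) and the immediate early genes Fos (0.02 ± 0.17) and Egr1 (0.03 ± 0.18) all had an adjusted p of 1. Of 37 lists tested, 14 were called, 7 upward and 7 downward, and only the proliferation call held whichever library was left out. The PPARα call was lost without PBS replicate 1 (median 0.05, adjusted p = 0.411), and its median was 0.41 without PBS replicate 3 and 0.13 without sensitized control replicate 2. The T cell median was −1.18 without sensitized control replicate 3, and its call was lost without sensitized control replicate 1 (−0.08, adjusted p = 0.263) or replicate 2 (−0.09, adjusted p = 0.147).

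The 30 min comparison with the sensitized controls asked what changed first after challenge. Cell cycle genes rose as a group: 16 of 17 measured members of the proliferation list had positive values, with a median of 0.49 (adjusted p = 1.2e-08; adjusted p = 0.37 with an estimated correlation). Top2a was at 99.6 ± 47.8 against 47.8 ± 5.44 CPM (1.06 ± 0.29). The S-phase cyclin Ccna2 was at 47.7 ± 6.01 against 30.1 ± 4.88 CPM (0.66 ± 0.20), and the proliferation marker Mki67 at 192 ± 48.4 against 128 ± 1.31 CPM (0.58 ± 0.22). Adjusted over the list alone, 8 of the 17 rose and 0 fell, and over all genes 0 passed. The mean log2 CPM of the list was 4.71 to 5.01 in the sensitized controls, which serve all 3 times, and 5.07 to 5.54 at 30 min. The PBS mice, at 5 to 5.3, overlapped the 30 min mice. Genes of drug and xenobiotic metabolism fell as a group, with all 16 negative, a median of −0.51 (adjusted p = 1.36e-07; adjusted p = 0.37 with an estimated correlation). Adjusted over the list alone 4 were lower, and 0 over all genes. These 4 were the glutathione transferases Gsta4 (−0.66 ± 0.17) and Gstm3 (−0.59 ± 0.20) and the cytochromes Cyp2c66 (−0.94 ± 0.30) and Cyp2c65 (−0.68 ± 0.24). The median of this list was −0.23 without sensitized control replicate 1, and its level at 30 min overlapped that in the PBS mice.

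Absorptive enterocyte genes were lower at 30 min in the list tests. The brush border list had all 19 members negative with a median of −0.37 (adjusted p = 4.58e-06; adjusted p = 0.642 with an estimated correlation). Among them were sucrase-isomaltase (Sis) at 3270 ± 446 against 4650 ± 540 CPM and the alkaline phosphatase Alpi at 318 ± 48.7 against 433 ± 50.3 CPM. The lipid absorption list had 15 of 16 negative and a median of −0.43 (adjusted p = 2.39e-06; adjusted p = 0.37 with an estimated correlation), with the fatty acid binding protein Fabp1 at 148 ± 60.7 against 270 ± 44.5 CPM. The PPARα list had all 16 negative and a median of −0.29 (adjusted p = 0.000121; adjusted p = 0.564 with an estimated correlation). In these 3 lists no member passed over all genes or adjusted over the list alone. The brush border median was −0.21 without sensitized control replicate 1 and the PPARα median −0.19 without sensitized control replicate 2. The 30 min levels of all 3 lists lay within the range of the unchallenged PBS mice: the mean log2 CPM of the brush border list was 8.54 to 8.77 at 30 min, 8.84 to 9.39 in the sensitized controls and 8.27 to 9.38 in the PBS mice. Genes of Paneth cells, the antimicrobial secretory cells at the crypt base, were higher, with 10 of 11 positive and a median of 0.62 (adjusted p = 0.000128; adjusted p = 0.493 with an estimated correlation). The lectin Itln1 was at 1540 ± 472 against 1010 ± 113 CPM and the α-defensin Defa30 at 2640 ± 900 against 1560 ± 241 CPM. Reads of the α-defensins can be shared between near-identical copies, so the values of single defensin genes are uncertain. The Paneth median was 0.39 without 30 min replicate 1, and the 30 min level of this list overlapped that in the PBS mice. It also overlapped that in the sensitized controls (mean log2 CPM of 7.65 to 8.6 at 30 min and 7.55 to 7.89 in these controls). In unchallenged PBS replicate 1 the brush border level was the lowest of the PBS mice (8.27). Its proliferation (5.3) and Paneth (8.25) levels were the highest of them. The shares of crypt and villus cells in each isolate were not measured, so the list changes at 30 min are not separated from such shares.

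Chaperone genes were also lower at 30 min. The heat shock list had 11 of 12 negative and a median of −0.34 (adjusted p = 2.22e-06; adjusted p = 0.37 with an estimated correlation), and 3 members were lower when adjusted over the list alone and 0 over all genes. These were the HSP70 co-chaperones Dnajb1 (−0.61 ± 0.16) and Dnaja1 (−0.47 ± 0.15) and the nucleotide exchange factor Hsph1 (−0.94 ± 0.27). The endoplasmic reticulum (ER) stress list had 12 of 14 negative and a median of −0.26 (adjusted p = 7.58e-05; adjusted p = 0.37 with an estimated correlation), with 0 members past either adjustment. Its median was −0.14 without sensitized control replicate 1 and −0.41 without 30 min replicate 1. At 30 min the heat shock level (mean log2 CPM of 6.97 to 7.09) lay below that of the PBS mice (7.32 to 7.53), while the ER stress levels overlapped. Erythroid markers had all 5 measured members negative and a median of −2.05 (adjusted p = 1.47e-06; adjusted p = 0.37 with an estimated correlation). The β-globin genes Hbb-bt (−2.14 ± 0.62) and Hbb-bs (−2.05 ± 0.62) and the α-globin gene Hba-a1 (−2.28 ± 0.71) were lower when adjusted over the list alone, and 0 passed over all genes. Globin copies share reads, so the split between them is uncertain. In 30 min replicate 1, markers of stromal and endothelial cells were high: the stromal list was called upward (adjusted p = 0.0133; adjusted p = 0.642 with an estimated correlation). Without that library its median was −0.08 (adjusted p = 0.374). Markers of macrophages and dendritic cells (median 0.65, adjusted p = 0.0307) and MHC class II genes (0.56, adjusted p = 0.0351) were also called upward, each with an adjusted p = 0.642 with an estimated correlation. With 1 library left out their medians reached 1.03 (without 30 min replicate 2) and 1.7 (without sensitized control replicate 3; 0.85 without 30 min replicate 2). At 30 min the levels of these lists overlapped those in the PBS mice. The mean log2 CPM of T, B and macrophage markers was 1.24 to 3.46 in the 30 min libraries and 1.72 to 3.32 in the sensitized controls. The macrophage call was lost without 30 min replicate 1 (0.08, adjusted p = 0.994) or replicate 3 (0.72, adjusted p = 0.106), and without sensitized control replicate 2 (0.42, adjusted p = 0.5) or replicate 3 (0.51, adjusted p = 0.0516). The MHC class II call was lost without 30 min replicate 1 (0.31, adjusted p = 0.212) or replicate 3 (0.41, adjusted p = 0.173), and without sensitized control replicate 1 (0.29, adjusted p = 0.291) or replicate 2 (0.15, adjusted p = 0.472).

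No single gene passed at 30 min in edgeR, where 755 had an unadjusted p under 0.05; DESeq2 called 6, limma-voom 0, and edgeR 1 without 30 min replicate 1. The genes with the smallest p (adjusted p = 0.876, not passing) were Abhd3 (−0.60 ± 0.12), the arylacetamide deacetylase Aadac (−0.49 ± 0.10; 110 ± 8.17 against 153 ± 2.09 CPM), Melk (0.94 ± 0.21; 16.9 ± 1.64 against 8.81 ± 0.706 CPM) and Eci3 (−0.82 ± 0.19). Then came G2e3 (0.83 ± 0.20), Espl1 (0.70 ± 0.17), Arl14 (−0.87 ± 0.21), the carotenoid-cleaving enzyme Bco2 (−0.61 ± 0.15), Gstk1 (−0.57 ± 0.14) and the mitotic kinesin Kif11 (0.63 ± 0.16). With the PBS mice as control these were smaller by over 1.5 times for Melk (0.19), Espl1 (0.16), G2e3 (0.43), Kif11 (0.30), Aadac (−0.3) and Gstk1 (−0.3). For Espl1 the value was 1.11 with a correction for transcript length. Il33 (−0.55 ± 0.45, adjusted p = 0.981), Mcpt1 (−0.49 ± 0.71, 0.991), Fos (−0.01 ± 0.17, 0.999) and Egr1 (0.08 ± 0.18, 0.992) did not pass. Of the 37 lists, 15 were called, 5 upward and 10 downward, and 9 kept the call whichever library was left out: the proliferation, xenobiotic, brush border, lipid absorption, PPARα, Paneth, heat shock, ER stress and erythroid lists.

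At 60 min after challenge the chaperone genes were lower than in the sensitized controls. Dnajb1 (ENSMUSG00000005483.10, a protein-coding gene on chromosome 8 from 83608193 to 83612653 in mm10) fell from 179 ± 31.2 to 82.0 ± 14 CPM (−1.12 ± 0.16, edgeR adjusted p = 0.0454). It was lower in all 3 challenged than in all 3 control libraries. The heat shock list had 11 of 12 negative and a median of −0.5 (adjusted p = 2.87e-06; adjusted p = 0.555 with an estimated correlation). Over all genes 1 of its members fell, and 6 fell when adjusted over the list alone, among them Dnaja1 (−0.68 ± 0.15), Hsph1 (−1.24 ± 0.28) and the co-chaperone Bag3 (−0.58 ± 0.14). The other two were the inducible HSP70 genes, Hspa1a with 13.4 ± 3.70 against 142 ± 153 CPM and Hspa1b with 22.6 ± 9.08 against 196 ± 177 CPM, which are near-identical copies and vary widely among the controls. Of the ER stress list, 13 of 14 were negative with a median of −0.31 (adjusted p = 4.99e-05; adjusted p = 0.555 with an estimated correlation), with 5 lower when adjusted over the list alone and 0 over all genes. Its leading member was Hspa5 (BiP), the main HSP70 of the ER, at 867 ± 49.6 against 1440 ± 107 CPM (−0.74 ± 0.15, adjusted p = 0.175). It was followed by Dnajb9 (−0.74 ± 0.16), Creld2 (−0.86 ± 0.20), Manf (−0.57 ± 0.17) and the transcription factor Ddit3 (−0.96 ± 0.30). In fry's directional test these 2 lists had an adjusted p of 0.0395 each. The ER stress median was −0.52 without 60 min replicate 1. At 60 min both lists lay below the PBS mice as well, at 6.52 to 6.91 against 7.32 to 7.53 for heat shock and 5.93 to 6.34 against 6.43 to 6.6 for ER stress (mean log2 CPM).

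Among secretory lineages at 60 min, all 13 goblet cell genes were negative with a median of −0.48 (adjusted p = 0.000676; adjusted p = 0.673 with an estimated correlation). Of these, 2 were lower when adjusted over the list alone and 0 over all genes. These were Clca1, a secreted mucus-processing protease, at 750 ± 30.9 against 1420 ± 451 CPM, and the mucus lectin Zg16 at 1070 ± 292 against 2180 ± 535 CPM. Paneth cell genes were higher, with 10 of 11 positive and a median of 0.56 (adjusted p = 0.000974; adjusted p = 0.673 with an estimated correlation). Itln1, at 2080 ± 673 against 1010 ± 113 CPM (1.05 ± 0.27), was the 1 member higher when adjusted over the list alone, and 0 passed over all genes. The proliferation list had 14 of 17 positive and a median of 0.34 (adjusted p = 0.000645; adjusted p = 0.673 with an estimated correlation). Mki67, Ccna2, Top2a and Ccnb1 were higher when adjusted over the list alone and 0 over all genes. The proliferation call was lost without 60 min replicate 1 (median 0.25, adjusted p = 0.0874). Immediate early genes had 14 of 17 negative and a median of −0.28 (adjusted p = 0.00192; adjusted p = 0.673 with an estimated correlation). Fosb, at 678 ± 221 against 1290 ± 154 CPM, was the 1 lower when adjusted over the list alone. That call was lost without 60 min replicate 3 (−0.1, adjusted p = 0.16), the library with 33.24% mitochondrially encoded counts, and the median was −0.16 without sensitized control replicate 1 and −0.47 without 60 min replicate 1. Interferon-stimulated genes had a median of −0.62 (adjusted p = 0.00314; adjusted p = 0.673 with an estimated correlation), lost without sensitized control replicate 3 (−0.38, adjusted p = 0.0963) or 60 min replicate 1 (−0.55, adjusted p = 0.0874). T cell markers had a median of −0.9 (adjusted p = 0.0464; adjusted p = 0.866 with an estimated correlation). That median was 0.09 without sensitized control replicate 3 (adjusted p = 0.921), and −0.59 without 60 min replicate 1 (adjusted p = 0.293) or replicate 2 (adjusted p = 0.533). At 60 min the levels of the goblet, Paneth, proliferation and immediate early lists overlapped those in the PBS mice, and those of the interferon and T cell lists lay below them.

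Dnajb1 was the 1 gene that passed at 60 min, while 1883 genes had an unadjusted p under 0.05; DESeq2 called 189 and limma-voom 0. In edgeR the count was 0 without sensitized control replicate 2, without sensitized control replicate 3 or without 60 min replicate 2, and 385 without 60 min replicate 1. Without 60 min replicate 3 it was 1 and without the 3 libraries with over 25% mitochondrially encoded counts it was 2, but Dnajb1 was not among them (−1 and −0.88, adjusted p = 0.231 and 0.761). Dnajb1 passed in 9 of 19 alternatives. Next in order of p, and not passing, was the chromatin remodelling subunit Smarcc1 (0.78 ± 0.13, adjusted p = 0.152). At an adjusted p of 0.175 were Kif11 (0.89 ± 0.16), Asxl1 (0.67 ± 0.12), the spindle protein Aspm (1.11 ± 0.22), Csrnp1 (−0.91 ± 0.18), Fam78a (−0.70 ± 0.14), Abhd3 (−0.58 ± 0.12), Hcfc1 (0.63 ± 0.13) and the topoisomerase Top3a (0.86 ± 0.18). With the PBS mice as control, Dnajb1 had −0.86 (adjusted p = 0.322), and Kif11 (0.56), Aspm (0.59) and Top3a (0.54) were smaller by over 1.5 times. Il33 (−0.47 ± 0.45, adjusted p = 0.699), Mcpt1 (−0.21 ± 0.71, 0.935), Fos (−0.21 ± 0.17, 0.626) and Egr1 (−0.02 ± 0.18, 0.983) did not pass. Of the 37 lists, 13 were called, 2 upward and 11 downward, and the heat shock, ER stress, goblet and Paneth calls held whichever library was left out.

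At 120 min the genes of the cholesterol synthesis list rose. All 17 measured members of the list had positive values, with a median of 0.88 (adjusted p = 5.54e-18; adjusted p = 0.115 with an estimated correlation). Of these, 11 rose over all genes and 16 when adjusted over the list alone. For the list, 1 further member was not analysed here. The epoxidase Sqle (ENSMUSG00000022351.14, chromosome 15 from 59315077 to 59331192 in mm10) rose from 84.4 ± 8.97 to 167 ± 22.5 CPM (0.99 ± 0.17, edgeR adjusted p = 0.017), and the squalene synthase Fdft1 from 80.2 ± 2.90 to 151 ± 12.7 CPM (0.91 ± 0.13, adjusted p = 0.00514). Also past the threshold were the enzymes Lss (1.04 ± 0.18), Cyp51 (0.97 ± 0.14), Msmo1 (0.96 ± 0.15), Idi1 (0.81 ± 0.19) and Nsdhl (0.74 ± 0.17). Insig1 (0.79 ± 0.18) also passed, which holds the SREBP regulators of this pathway in the ER. Srebf2, which encodes the main such regulator, did not pass over all genes (0.42). In fry's directional test the list had an adjusted p of 0.000653, and its median stayed between 0.81 and 0.91 with any 1 library left out.

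**Figure D1:**
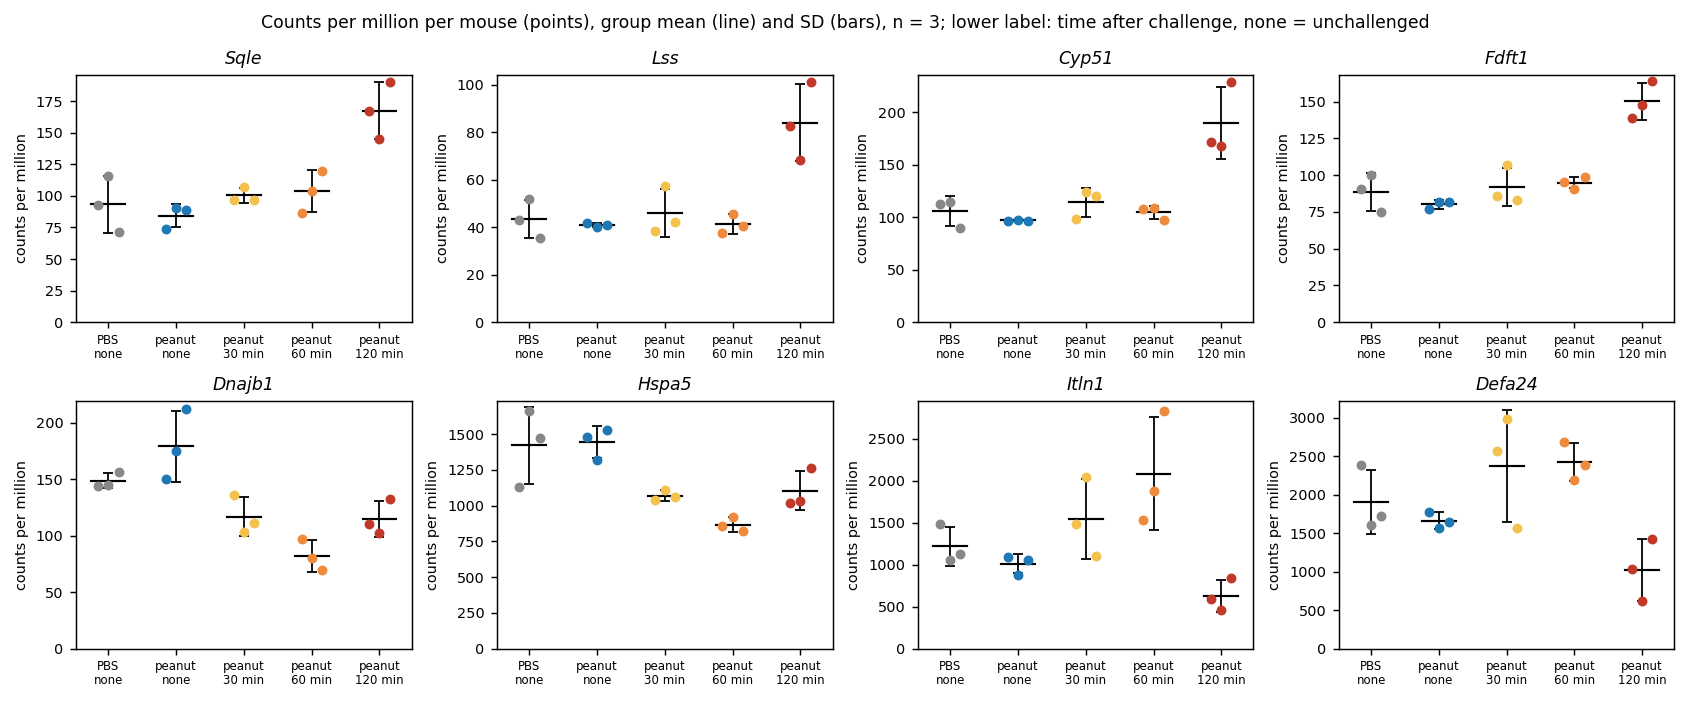
CPM of 8 genes in each of the 15 mice, by group (points, 1 per mouse; line, mean; bars, SD; n = 3 per group). The mean of Sqle is 84.4 CPM in the sensitized controls and 167 CPM at 120 min, while Itln1 lies at 2080 CPM at 60 min and 631 CPM at 120 min.

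By the rule for naming genes, 11 of the 12 largest rises at 120 min are given here. Largest was Hif3a, a member of the hypoxia-inducible factor family (2.90 ± 0.46; 5.97 ± 2.11 against 0.778 ± 0.432 CPM; ENSMUSG00000004328.15, chromosome 7 from 17031507 to 17062427). Also among them were the fibroblast growth factor receptor Fgfr4 (1.77 ± 0.31), Fam43a (1.62 ± 0.29), the linker histone gene Hist1h1d (1.48 ± 0.28), Clca3a1 (1.39 ± 0.30) and the taurine transporter Slc6a6 (1.36 ± 0.22; 546 ± 114 against 212 ± 42.9 CPM). The others were Ddah1 (1.30 ± 0.22), which breaks down methylated arginines, the filamin partner Rflnb (1.28 ± 0.16, adjusted p = 0.00284), the acetyl-CoA acetyltransferase Acat2 (1.19 ± 0.24), Gp1bb (1.17 ± 0.20) and the GPI-anchor deacylase Pgap1 (1.13 ± 0.15, adjusted p = 0.00299). Among the 12 largest falls, Cyp2u1, a cytochrome P450 that hydroxylates fatty acids (ENSMUSG00000027983.13, chromosome 3 from 131288441 to 131303227), fell from 48.1 ± 0.533 to 20.4 ± 2.03 CPM (−1.24 ± 0.14, adjusted p = 0.00162). Another receptor gene for fibroblast growth factors, Fgfr2, fell from 28.8 ± 2.66 to 11.4 ± 2.44 CPM (−1.34 ± 0.28). The remaining falls were Dennd4b (−1.75 ± 0.34), Fam214a (−1.67 ± 0.24), Rfesd (−1.51 ± 0.25) and Trim38 (−1.50 ± 0.32). Smaller were the ciliary gene Tctn3 (−1.49 ± 0.30), the pseudogene Zfp862-ps (−1.46 ± 0.32), Zkscan7 (−1.27 ± 0.22), Sspo (−1.25 ± 0.24), the calcineurin regulator Rcan3 (−1.23 ± 0.22) and Parp11 (−1.22 ± 0.27).

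**Figure D2:**
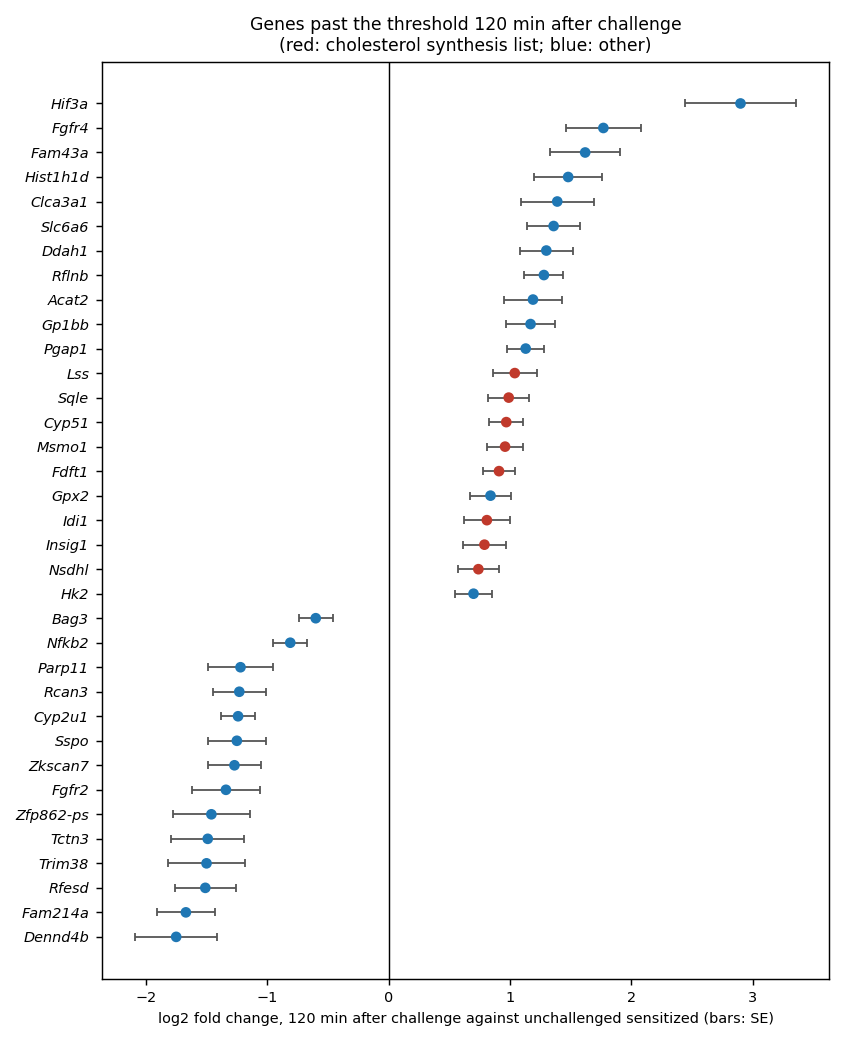
Log2 fold change at 120 min against the sensitized controls for 35 of the genes past the threshold that the naming rule takes (points; bars, standard error; red, 8 members of the cholesterol synthesis list). Values run from 2.90 for Hif3a to −1.75 for Dennd4b.

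Other stress and transport groups rose at 120 min. All 12 measured glucocorticoid-regulated genes had positive values, with a median of 0.75 (adjusted p = 5.81e-05; adjusted p = 0.451 with an estimated correlation); 5 rose when adjusted over the list alone and 0 over all genes. Fkbp5, a co-chaperone of the glucocorticoid receptor, was at 294 ± 149 against 44.1 ± 30.4 CPM (2.73 ± 0.72, adjusted p = 0.094). The transcription factor Zbtb16 was at 14.8 ± 8.15 against 1.28 ± 1.11 CPM, and the kinase Sgk1 at 233 ± 94.5 against 86.4 ± 53.1 CPM. NRF2-dependent antioxidant genes had a median of 0.41 (adjusted p = 0.00156; adjusted p = 0.375 with an estimated correlation). Over all genes 1 rose, the glutathione peroxidase Gpx2 (186 ± 3.29 to 333 ± 84.5 CPM, 0.84 ± 0.17), and 6 when adjusted over the list alone, among them glutathione reductase (Gsr, 0.70 ± 0.18) and Nqo1 (0.54 ± 0.17). Ion transport genes had 15 of 16 positive and a median of 0.27 (adjusted p = 0.00361; adjusted p = 0.666 with an estimated correlation). The potassium channels Kcnn4 (0.74 ± 0.20) and Kcnq1 (0.58 ± 0.19) and the bicarbonate transporter Slc4a4 (0.50 ± 0.17) were higher when adjusted over the list alone and 0 over all genes. The proliferation list had all 17 positive and a median of 0.44 (adjusted p = 5.81e-05; adjusted p = 0.666 with an estimated correlation), with 0 past either adjustment and Cdc20 leading (0.74 ± 0.23). The proliferation median was 0.18 without 120 min replicate 3 (adjusted p = 0.0167). Hypoxia and glycolysis genes had a median of 0.18 (adjusted p = 0.0235; adjusted p = 0.375 with an estimated correlation), a call lost without 120 min replicate 1 (0.1, adjusted p = 0.0674); without sensitized control replicate 1 and replicate 2 the median was 0.32 and 0.11. Hexokinase 2 (Hk2) rose from 76.7 ± 8.22 to 125 ± 9.97 CPM (0.70 ± 0.15), and Hk2, Pfkfb3 (1.42 ± 0.32), Pgk1 (0.36 ± 0.11) and Slc2a1 (0.52 ± 0.17) were higher when adjusted over the list alone. In the tight junction list, which was not called (median 0, adjusted p = 0.446), 1 member passed over all genes and 2 were higher when adjusted over the list alone, among them the pore-forming claudin Cldn2 (0.55 ± 0.14). At 120 min the levels of the cholesterol, glucocorticoid, NRF2 and hypoxia lists lay above those in the PBS mice too, and those of the proliferation and ion transport lists overlapped them.

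Goblet, Paneth, T cell and B cell markers were lower at 120 min in the list tests. All 13 goblet genes were negative with a median of −0.72 (adjusted p = 3.22e-05; adjusted p = 0.666 with an estimated correlation). Adjusted over the list alone 6 were lower, and 0 over all genes. Among the 6 were the goblet cell transcription factors Spdef (−0.72 ± 0.20) and Foxa3 (−0.78 ± 0.23), and Clca1 (755 ± 86.4 against 1420 ± 451 CPM). Paneth genes had 10 of 11 negative and a median of −0.68 (adjusted p = 0.00279; adjusted p = 0.666 with an estimated correlation), with 0 past either adjustment. The Paneth call was lost without 120 min replicate 2 (−0.46, adjusted p = 0.126). Itln1 was at 631 ± 190 against 1010 ± 113 CPM and the ribonuclease Ang4 at 49.8 ± 22.4 against 107 ± 11.3 CPM. T cell markers were all negative (16 of 16) with a median of −1.68 (adjusted p = 5.81e-05; adjusted p = 0.666 with an estimated correlation) and 0 past either adjustment. Without sensitized control replicate 3 that median was −0.78. B and plasma cell markers had all 12 negative and a median of −1.82 (adjusted p = 0.00288; adjusted p = 0.668 with an estimated correlation), lost without sensitized control replicate 3 (−0.27, adjusted p = 0.219). Of these, 3 were lower when adjusted over the list alone and 0 over all genes. These were the antibody chains Igha (210 ± 116 against 742 ± 125 CPM) and Igkc (92.5 ± 50.1 against 372 ± 150 CPM) and the joining chain Jchain (39.4 ± 17.2 against 133 ± 25.3 CPM). The mean log2 CPM of T, B and macrophage markers was 0.66 to 1.71 in the 120 min libraries and 1.72 to 3.32 in the sensitized controls.

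Several inflammatory and stress lists fell with calls that a single library ended. The heat shock list had a median of −0.28 (adjusted p = 0.00677; adjusted p = 0.666 with an estimated correlation). Bag3 fell (−0.60 ± 0.14) and 3 members were lower when adjusted over the list alone. The heat shock call was lost without 120 min replicate 1 (−0.27, adjusted p = 0.0586) or replicate 2 (−0.32, adjusted p = 0.0768), and its median was −0.15 without sensitized control replicate 3. For NF-κB and inflammatory genes the median was −0.37 (adjusted p = 0.0267; adjusted p = 0.666 with an estimated correlation). The NF-κB subunit Nfkb2 fell (−0.81 ± 0.14) and was the 1 member past both adjustments. The list call was lost without sensitized control replicate 1 (−0.3, adjusted p = 0.0523), 120 min replicate 2 (−0.45, adjusted p = 0.0961) or replicate 3 (−0.3, adjusted p = 0.0773). Interferon-stimulated genes had a median of −0.59 (adjusted p = 0.0199; adjusted p = 0.668 with an estimated correlation), lost without sensitized control replicate 3 (−0.19, adjusted p = 0.242) or 120 min replicate 2 (−0.5, adjusted p = 0.141). Epithelial type 2 response genes, which share Clca1, Itln1 and Ang4 with the secretory lists, had a median of −0.53 (adjusted p = 0.0235; adjusted p = 0.375 with an estimated correlation). That call was lost without sensitized control replicate 3 (−0.64, adjusted p = 0.0769) or 120 min replicate 2 (−0.5, adjusted p = 0.103). Enteroendocrine genes had a median of −0.59 (adjusted p = 0.0418; adjusted p = 0.86 with an estimated correlation). Their call was lost without sensitized control replicate 1 (−0.6, adjusted p = 0.0545), replicate 2 (−0.55, adjusted p = 0.111) or 120 min replicate 2 (−0.32, adjusted p = 0.578), and the median was −0.9 without 120 min replicate 3. At 120 min the levels of the goblet, Paneth, T cell, B cell, NF-κB, interferon and type 2 lists lay below those in the PBS mice too, and those of the heat shock and enteroendocrine lists overlapped them.

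The lists that were not called at 120 min were those of tuft cells (median −0.74, adjusted p = 0.0505), mitochondrially encoded genes (−0.51, 0.0505), macrophages and dendritic cells (−0.21, 0.229), circadian genes (0.37, 0.252), erythroid cells (−0.91, 0.28), the brush border (0.16, 0.29), ER stress (−0.14, 0.29) and antimicrobial defence (0.22, 0.376). Also not called were those of eicosanoid and histamine metabolism (median −0.61, adjusted p = 0.491), mast cells (−0.97, 0.491), stem cells (−0.07, 0.52), villus tip (0.09, 0.571), PPARα targets (−0.11, 0.571), allergy receptors (−0.16, 0.571), granulocytes (−0.02, 0.571) and xenobiotic metabolism (0.03, 0.613). The last were stromal and endothelial cells (median −0.07, adjusted p = 0.626), immediate early genes (−0.05, 0.656), lipid absorption (0.04, 0.811), MHC class II (−0.46, 0.811) and p53 targets (−0.07, 0.883). Too few genes were measured to test the lists of AHR targets (2 of 7; Tiparp 0.08 and Nqo1 0.54), pancreas (1 of 11; Cela1 0.46) and smooth muscle and nerve (2 of 10, median −0.21). Il33 (0.43 ± 0.44, adjusted p = 0.667), Mcpt1 (−1.89 ± 0.75, 0.218), Fos (0.04 ± 0.17, 0.935) and Egr1 (−0.17 ± 0.18, 0.68) did not pass.

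In edgeR, 188 genes passed at 120 min, 109 higher and 79 lower (58% higher), with a median absolute log2 fold change of 0.79 and 51 changed more than 2-fold. In all 188 the treated and control libraries did not overlap. Chance alone gives this for 10% of unselected genes with 3 against 3, but these were selected by p in the same libraries, so setting one against the other is not a test. Of the 188, 4 are gene models with only a number for a name and 2 are immunoglobulin or T cell receptor segments. DESeq2 called 846 genes and limma-voom 167. The count fell to 12, 16 and 7 without sensitized control replicate 1, 2 and 3, to 12 and 13 without 120 min replicate 1 and 3. It fell to 7 without the 3 libraries with over 25% mitochondrially encoded counts, to 34 with a correction for transcript length and to 26 with the immune marker score as a covariate. Of those 3 libraries only sensitized control replicate 3 is in this comparison, so the count of 7 without them is not separate from that without it alone. All of the 188 kept their sign in each of these settings. Since their treated and control libraries did not overlap, a change of sign was hardly possible, so this is no separate support. Rflnb, Pgap1 and Cyp2u1 kept their call in all 19 alternatives.

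**Figure D3:**
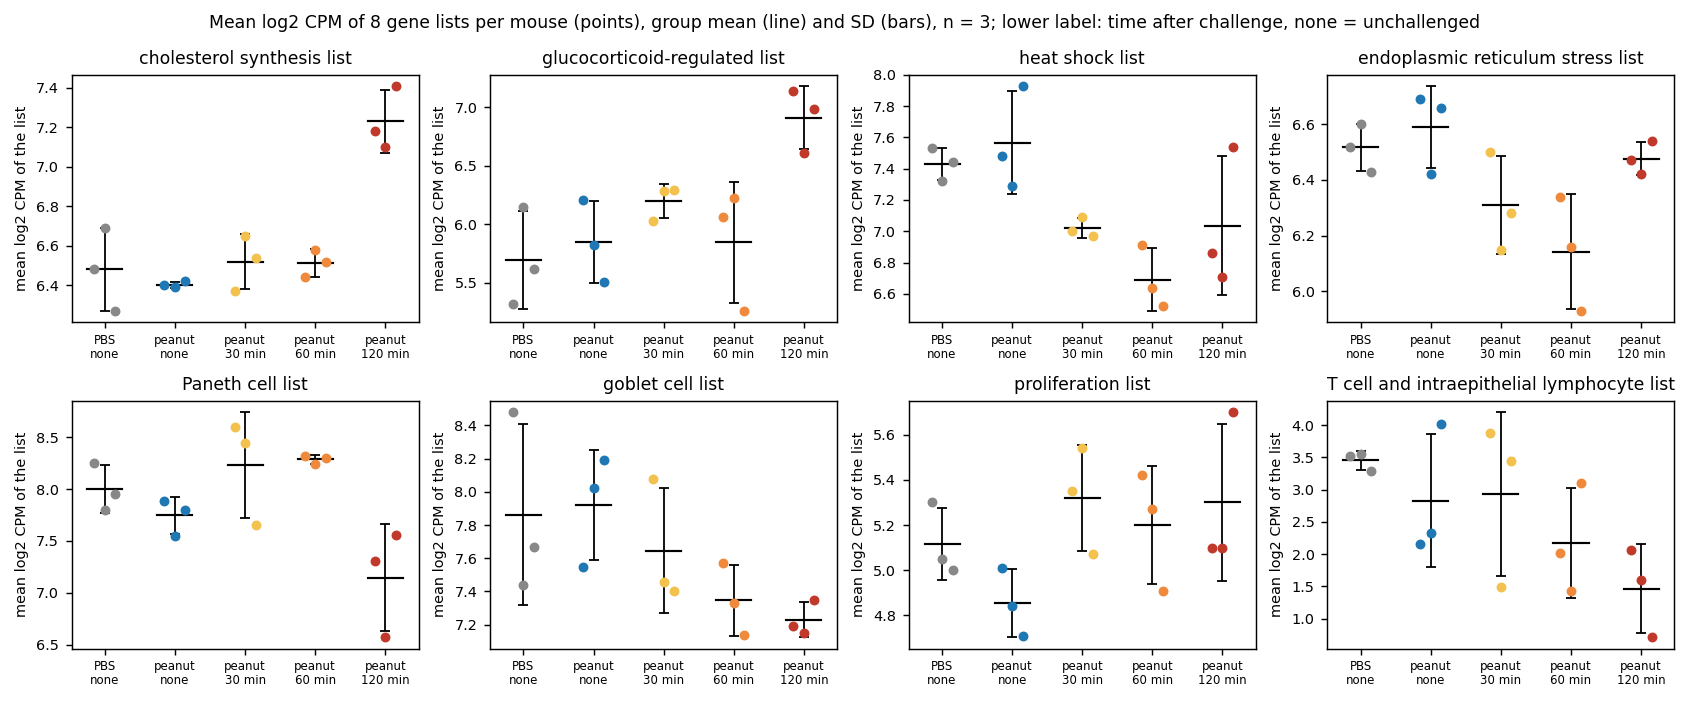
Mean log2 CPM of 8 gene lists in each of the 15 mice, by group (points, 1 per mouse; line, mean; bars, SD; n = 3 per group). Against the sensitized controls the median log2 fold change of the cholesterol list at 120 min was 0.88, and that of the Paneth list was 0.56 at 60 min and −0.68 at 120 min.

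Averaged over the 3 times, the cholesterol and proliferation lists were higher and the heat shock, goblet, ER stress and erythroid lists lower than in the sensitized controls, whichever library was left out. The list medians were 0.33 for cholesterol synthesis (adjusted p = 2.18e-09), 0.4 for proliferation (8.46e-08), −0.38 for heat shock (1.02e-06), −0.5 for goblet cells (8.88e-06), −0.2 for ER stress (0.000354) and −1.37 for erythroid markers (0.000465). With an estimated correlation the adjusted p for the average were 0.456, 0.502, 0.456, 0.618, 0.456 and 0.52, in the same order. The cholesterol list was called at 120 min but not at 30 min (median 0.16, adjusted p = 0.0512) or 60 min (0.13, adjusted p = 0.102). The ER stress list (−0.14, adjusted p = 0.29) and the erythroid list (−0.91, adjusted p = 0.28) were called at 30 and 60 but not at 120 min. The erythroid call at 60 min was lost without 60 min replicate 1 (−0.71, adjusted p = 0.132). For the average, 7 cholesterol and 5 proliferation genes were higher when adjusted over the list alone. By the same adjustment 7 heat shock, 5 goblet, 3 ER stress and 3 erythroid genes were lower, while 0 genes passed over all genes. The smallest p belonged to Cyp2u1 (−0.71 ± 0.11) and Dnajb1 (−0.79 ± 0.12), both at adjusted p = 0.0677 in edgeR and lower in all 9 challenged than in all 3 control libraries. They were followed, also not passing, by Smarcc1 (0.64 ± 0.11), Fam78a (−0.64 ± 0.11), Nfkb2 (−0.59 ± 0.11), the ER ubiquitin ligase Syvn1 (−0.58 ± 0.11), Rassf6 (−0.72 ± 0.14), Kif11 (0.66 ± 0.13), Csrnp1 (−0.70 ± 0.14) and Sspo (−0.92 ± 0.18). With the PBS mice as control, Cyp2u1 (−0.46), Dnajb1 (−0.52), Smarcc1 (0.41), Nfkb2 (−0.38), Syvn1 (−0.3) and Kif11 (0.33) were smaller by over 1.5 times. Il33 (−0.20 ± 0.36, adjusted p = 0.877), Mcpt1 (−0.86 ± 0.56, 0.62), Fos (−0.06 ± 0.14, 0.896) and Egr1 (−0.04 ± 0.15, 0.948) did not pass. With 1573 genes at an unadjusted p under 0.05, edgeR called 0 for the average, DESeq2 172 and limma-voom 0. Without sensitized control replicate 2, 30 min replicate 1, 60 min replicate 1 or 60 min replicate 3, edgeR called 1, 3, 5 and 5.

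The joint test of all 3 times asked which genes changed at any time. It called 78 genes, of which 62 had their largest change at 120 min, 11 at 60 min and 5 at 30 min, and 59 were also called at 120 min alone. Among those with the smallest p, named after their values were seen, Pgap1 changed by −0.06 ± 0.15 at 30 min, 0.31 ± 0.14 at 60 min and 1.13 ± 0.15 at 120 min. The RNA-editing enzyme gene Apobec1 changed by −0.23 ± 0.16, −0.09 ± 0.16 and 1 ± 0.16. DESeq2 called 1013 genes and limma-voom 45 in this test. The edgeR count was 12, 12 and 20 without sensitized control replicate 1, 2 and 3, and 50, 49 and 51 without 30 min replicate 1, 2 and 3. It was 356, 21 and 119 without 60 min replicate 1, 2 and 3, and 0 without 120 min replicate 1 or replicate 3. It was 5 with the immune marker score as a covariate, 25 with the correction for transcript length, 30 with the groups compared alone and 176 with 1 surrogate variable. With the mitochondrially encoded share as a covariate, and without the 3 libraries with over 25% of such counts, it was 38.

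Between 30 and 60 min no gene passed, so the differences in list calls between these times are not differences shown by a gene test. The genes with the smallest p (adjusted p = 0.863, not passing) were the ribosomal protein gene Rps27 (1.37 ± 0.466 CPM at 60 min and 3.78 ± 1.21 CPM at 30 min), the osmotic response factor Nfat5 (64.2 ± 6.09 and 47.6 ± 4.11 CPM) and Cyp2c55 (5.86 ± 2.65 and 1.52 ± 0.597 CPM). In the same order, others were Ly6c1 (0.145 ± 0.206 and 1.59 ± 1.24 CPM), the chemokine Cxcl2 (0.477 ± 0.318 and 2.64 ± 2.51 CPM) and the endothelial receptor Tek (0.0181 ± 0.0314 and 0.968 ± 1.17 CPM). The rest were Cyp2c66 (27.7 ± 6.96 and 13 ± 1.51 CPM), Gnl3l (42.2 ± 3.80 and 31.7 ± 2.41 CPM), Timp2 (1.33 ± 0.262 and 5.47 ± 5.50 CPM) and Klc1 (15.5 ± 2.35 and 22.6 ± 2.58 CPM). Il33 (0.08 ± 0.45, adjusted p = 0.982), Mcpt1 (0.28 ± 0.71, 0.951), Fos (−0.20 ± 0.17, 0.863) and Egr1 (−0.09 ± 0.18, 0.938) did not pass. With 667 genes at an unadjusted p under 0.05, edgeR called 0 (1 without 30 min replicate 1), DESeq2 5 and limma-voom 0. Of 37 lists 6 were called, with a lowest adjusted p of 0.958 with an estimated correlation, and none kept its call whichever library was left out.

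From 60 to 120 min Paneth cell genes fell and cholesterol genes rose. Itln1 (ENSMUSG00000038209.12, chromosome 1 from 171518122 to 171535294 in mm10) fell from 2080 ± 673 to 631 ± 190 CPM (−1.72 ± 0.27, edgeR adjusted p = 0.019). Ang4 fell from 222 ± 100 to 49.8 ± 22.4 CPM (−2.15 ± 0.43) and the α-defensin Defa24, subject to shared reads, from 2420 ± 249 to 1020 ± 403 CPM (−1.25 ± 0.27). The Paneth list had a median of −1.25 (adjusted p = 3.86e-07; adjusted p = 0.418 with an estimated correlation), with 5 lower over all genes and 9 lower and 1 higher when adjusted over the list alone. Of the cholesterol list (median 0.69, adjusted p = 7.54e-13; adjusted p = 0.106 with an estimated correlation), 9 rose over all genes and 16 when adjusted over the list alone. The prenyl synthase Fdps went from 42.6 ± 5.97 to 99.2 ± 32.1 CPM (1.22 ± 0.22). Angptl4, an inhibitor of lipoprotein lipase, rose from 28.6 ± 7.43 to 93.7 ± 35.3 CPM (1.71 ± 0.31). So did the bile acid exporter subunit Slc51b (1.49 ± 0.24), Fgfr4 (1.45 ± 0.30), the vasoactive peptide adrenomedullin (Adm, 1.41 ± 0.28) and Clca3a1 (1.31 ± 0.30). The largest falls outside the Paneth list, by the rule for naming genes, were Insrr (−1.77 ± 0.35), Habp2 (−1.59 ± 0.33), Samd5 (−1.54 ± 0.24) and Ccdc18 (−1.50 ± 0.33). The glucose transporter Slc2a1 (0.91 ± 0.17), Gpx2 (0.80 ± 0.17), Gsta4 (1.01 ± 0.17) and Myc (1 ± 0.21) rose and the stem cell receptor Lgr5 fell (−1.09 ± 0.25). The NRF2 list (median 0.57, adjusted p = 8.25e-05; adjusted p = 0.106 with an estimated correlation) was higher at 120 min. So were the hypoxia list (0.32, adjusted p = 0.00106; adjusted p = 0.106 with an estimated correlation) and the glucocorticoid list (0.76, adjusted p = 0.000133; adjusted p = 0.5 with an estimated correlation). Adjusted over the list alone, 7, 4 and 5 of their members were higher, against 1, 2 and 0 over all genes. These 5 lists kept the call whichever library was left out, as did the ER stress list (0.38, adjusted p = 0.00887; adjusted p = 0.68 with an estimated correlation) and the B cell list (−1.45, adjusted p = 0.00217; adjusted p = 0.699 with an estimated correlation). Without 60 min replicate 3 the medians were 0.37 for NRF2, 0.46 for glucocorticoids, 0.19 for ER stress and −0.86 for B cells.

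In this comparison of 60 with 120 min, edgeR called 168 genes, 88 higher and 80 lower at 120 min, with 2954 at an unadjusted p under 0.05; DESeq2 called 951 and limma-voom 179. Without 60 min replicate 1, 2 or 3 the count was 1151, 2 and 2, and without 120 min replicate 1, 2 or 3 it was 0, 298 and 0. It was 4 with the mitochondrially encoded share as a covariate, 6 without the 3 libraries with over 25% of such counts, 0 with the groups compared alone, 46 with the correction for transcript length, 52 with 1 surrogate variable and 101 with the immune marker score. The balance turned toward lower genes in 4 alternatives: 19 higher and 27 lower with the length correction, 37 and 64 with the immune marker score, 110 and 188 without 120 min replicate 2, and 75 and 97 with the mitochondrially encoded, immunoglobulin and haemoglobin genes removed. In all 18 alternatives each of the 168 genes that was tested kept its sign, and their median absolute log2 fold change was 0.79 to 0.94 (0.88 with all libraries). In all 168 the libraries of both times did not overlap, so a change of sign was hardly possible and this is no separate support. The mitochondrially encoded list itself was lower at 120 than at 60 min (median −0.77, adjusted p = 0.0176; adjusted p = 0.699 with an estimated correlation). That call was lost without 60 min replicate 3 (−0.02, adjusted p = 0.945) or 120 min replicate 1 (−0.79, adjusted p = 0.055). Il33 (0.90 ± 0.45, adjusted p = 0.292), Mcpt1 (−1.68 ± 0.75, 0.241), Fos (0.25 ± 0.17, 0.423) and Egr1 (−0.15 ± 0.18, 0.676) did not pass.

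Between 30 and 120 min the cholesterol list (median 0.74, adjusted p = 1.65e-15; adjusted p = 0.0907 with an estimated correlation) rose, with 9 members higher over all genes and 16 when adjusted over the list alone. The Paneth list (median −1.3, adjusted p = 4e-07; adjusted p = 0.42 with an estimated correlation) fell, with 5 lower over all genes and 9 lower and 1 higher when adjusted over the list alone. In edgeR, Itln1 fell from 1540 ± 472 to 631 ± 190 CPM (−1.29 ± 0.27). The largest rises were Angptl4 (1.78 ± 0.31), the glycolytic regulator Pfkfb3 (1.62 ± 0.32; 28.0 ± 7.47 to 86.2 ± 19.7 CPM) and Syt12 (1.54 ± 0.32). Next were Fam43a (1.52 ± 0.28), the EGF receptor ligand epiregulin (Ereg, 1.51 ± 0.33; 30.9 ± 9.72 to 88.4 ± 29.0 CPM) and Clca3a1 (1.46 ± 0.30). The largest falls were Rftn1 (4.70 ± 2.18 to 0.572 ± 0.171 CPM), the lymphocyte activation marker Cd69 (8.15 ± 3.86 to 1.43 ± 0.415 CPM), Pcbp4 (−2.28 ± 0.49), Rinl (−2.24 ± 0.47), Tnfaip8l3 (−1.94 ± 0.42) and Zfp862-ps (−1.81 ± 0.32). T cell markers fell with them (median −1.82, adjusted p = 1.2e-05; adjusted p = 0.526 with an estimated correlation). The sodium-hydrogen exchanger Slc9a3 rose (1.03 ± 0.22; 108 ± 15.9 to 219 ± 81.0 CPM). The brush border list was higher at 120 min (0.5, adjusted p = 1.44e-05; adjusted p = 0.526 with an estimated correlation). So were the xenobiotic (0.44, adjusted p = 1.87e-05; adjusted p = 0.526 with an estimated correlation), NRF2 (0.47, adjusted p = 7.08e-05; adjusted p = 0.123 with an estimated correlation) and hypoxia lists (0.46, adjusted p = 2e-04; adjusted p = 0.0907 with an estimated correlation). All these list calls held whichever library was left out, though without 120 min replicate 1 the brush border median was 0.31 and the hypoxia median 0.3.

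The comparison of 30 with 120 min called 151 genes in edgeR, 89 higher and 62 lower at 120 min, with 2642 at an unadjusted p under 0.05; DESeq2 called 838 and limma-voom 150. The count was 15, 59 and 52 without 30 min replicate 1, 2 and 3, and 4, 67 and 37 without 120 min replicate 1, 2 and 3. It was 5 with the immune marker score as a covariate (4 of them among the 151), 4 with the groups compared alone, 32 with the correction for transcript length, 277 with 1 surrogate variable and 315 without the 3 libraries with over 25% mitochondrially encoded counts. There were more lower than higher genes without 30 min replicate 1 (6 higher, 9 lower) or replicate 2 (22 and 37), with the immune marker score (2 and 3) and in DESeq2 (411 and 427). In all 18 alternatives each of the 151 genes that was tested kept its sign, with a median absolute log2 fold change of 0.81 to 0.91 (0.86 with all libraries). The libraries of both times did not overlap in any of the 151, so here too kept signs are no separate support. Il33 (0.98 ± 0.45, adjusted p = 0.282), Mcpt1 (−1.40 ± 0.75, 0.351), Fos (0.05 ± 0.17, 0.902) and Egr1 (−0.24 ± 0.18, 0.514) did not pass.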

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

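The differences between times were tests planned beforehand. Of the tests weighed here, those of the brush border, glucocorticoid, immediate early and 4 non-epithelial lists, the heat shock levels of single libraries, the covariates and the removal of 3 libraries were chosen only after the result was seen. The test of the difference between times itself singled out 168 genes from 60 to 120 min and 151 genes from 30 to 120 min. It also singled out 4 lists, past both camera and fry. Their medians from 60 and from 30 min were −1.25 and −1.3 for Paneth cells and 0.69 and 0.74 for cholesterol synthesis. They were 0.32 and 0.46 for hypoxia and glycolysis and 0.57 and 0.47 for NRF2 targets. With an estimated correlation the lowest adjusted p among these was 0.0907. In the paragraphs that follow, the SE of a median or of a margin came from 2000 bootstrap draws over genes. Such an SE holds no spread between mice.

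The 188 genes changed at 120 min could reflect fewer immune cells, RNA quality or a rise in glucocorticoids. Against fewer immune cells as the cause of the cholesterol rises, that list exceeded the brush border list by 0.72 (SD of the brush border genes 0.32). It was picked after its rise was seen, and the other rises are not covered. The immune scores at 120 min (0.66 to 1.71) lay below those of the sensitized controls (1.72 to 3.32). In a fit with a mean per group, the slope for the score comes from variation within groups. Since the 2 ranges did not overlap, carrying that slope across them is an extrapolation, and a fit with it cannot decide on immune cells. With the immune score the called falls kept 100.5% of their median (−0.89 to −0.9, SE 0.05 over genes, not mice) and the rises went from 0.69 to 0.64. The call ended for most genes there (26 called, 85 of the 188 at an adjusted p under 0.1); the rises shrank, the median SE went from 0.16 to 0.17 and 1 residual degree of freedom was lost, but which of these ended it was not tested. With the mitochondrially encoded share as covariate the called genes kept 95% of their median change (0.79 to 0.75). That share was 13.76% to 16.6% at 120 min and 17.15% to 26.73% in the sensitized controls. Its slope also came from variation within groups and was carried across ranges that did not overlap, so RNA quality stays open. A rise in glucocorticoids stays open as a hypothesis: the glucocorticoid list was 1.14 higher on the log2 scale in the 3 libraries at 120 min (lowest 6.61) than in the 6 unchallenged ones (highest 6.21; exact two-sided permutation p = 0.0119, the smallest that 84 permutations can give), a p not adjusted for picking this list among 40 after its rise was seen, and peanut, gavage, handling and time of day are not separated here.

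Lower chaperone genes at 60 min could come from a drop in body temperature, from 1 library, or from weaker stress while cells were released. Without 60 min replicate 3 the heat shock median was −0.4 against −0.5, a narrow margin over the bound set beforehand. The SE was 0.27 for that median and 0.13 for the margin, over genes and not mice. The levels in 60 min replicates 1 and 2 (mean log2 CPM of 6.91 and 6.64) also lay below all 6 unchallenged libraries (lowest 7.29). These levels argue against replicate 3 as the whole cause. The cold-induced genes Cirbp (−0.21 ± 0.24, edgeR adjusted p = 0.765) and Rbm3 (0.16 ± 0.15, adjusted p = 0.71) had a mean of −0.03 (SE 0.14), too close to 0 to decide on temperature. The immediate early list lay 0.22 above the heat shock list, within the SD of its genes (0.33), so weaker dissociation stress stays open. A response of the epithelium to peanut was not tested apart from these.

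Lower T and B cell markers at 120 min could come from 1 immune-rich control library or from fewer non-epithelial cells of every kind. Without sensitized control replicate 3 the T cell median was −0.78 against −1.68. It lay within the SE (0.13, over genes and not mice) of the bound of −0.84 set beforehand, so the part played by that library stays open. The highest of the 4 non-epithelial medians was −0.07 for stromal cells (SE 0.45, over genes and not mice). The others were −1.68 for T cells, −1.82 for B cells and −0.21 for macrophages, which leaves a general loss open. The most abundant genes of these lists were Ptprc (39.4 CPM), Igha (782 CPM), Csf1r (7.9 CPM) and Col3a1 (4.28 CPM). A movement of lymphocytes after challenge was not tested.

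For 3 libraries against 3, the 10 splits are too few for a share under 0.05. Where the real count is 0, every split gives as many, so such a tally (10 of 10) was fixed beforehand and says nothing about chance. Sensitization called 0 genes (highest other 1), 30 min 0 (highest other 21), 60 min 1 (5 of 10, highest other 1) and 120 min 188 (1 of 10, highest other 0). Between 30 and 60 min there were 0 (highest other 13), between 60 and 120 min 168 (1 of 10, highest other 1) and between 30 and 120 min 151 (1 of 10, highest other 0). The splits with 21 and 13 genes against 0 point to a structure of the samples beside the groups. The split with 21 set sensitized control replicates 1 and 2 and 30 min replicate 2 apart, whose mean log2 CPM of T, B and macrophage markers (2.1, 1.72 and 1.24) lay below that of sensitized control replicate 3 and 30 min replicates 1 and 3 (3.32, 3.46 and 3.1). With that score as a covariate edgeR again called 0 genes at 30 min (941 at an unadjusted p under 0.05). In the split with 13 these scores overlapped (3.46, 1.83 and 3.1 against 1.79, 2.87 and 1.24). For the average after challenge, with 0 genes, the tally (100 of 100 drawn splits of the 12 libraries) was fixed in the same way. Its highest other split, with 461 genes, set the 3 libraries of 120 min apart, so it follows one of the groups. Another with 367 set apart 60 min replicates 2 and 3 with 30 min replicate 2, which points to a structure of the samples beside the groups. For the joint test, 2 of 100 drawn splits gave as many as the 78 genes (highest other 110, more than the real count). That share is under 0.05 for this test alone and is not adjusted over the 9 results split in this way. The 78 became 0 without 120 min replicate 1 or replicate 3, so chance is not excluded.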

How the results depend on the processing

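The covariates for immune markers and mitochondrially encoded share and the removal of the 3 libraries with over 25% of such counts were tests chosen only after the data were seen. Settings that moved a count of called genes by more than 1.5 times gave the values below, and the cause was not tested. Sensitization (0 genes) and 30 min (0) each gave 6 with DESeq2. The 1 gene at 60 min became 49 with no filter, 0 with the length offset, 2 with 1 surrogate variable, 0 with the immune score, 7 with the mitochondrial share, 2 without the 3 libraries, 0 with the groups compared alone, 0 with limma-voom, 189 with DESeq2 and 0 with PBS mice as control. The 188 at 120 min became 34 with the length offset (33 shared), 427 with 1 surrogate variable (188 shared), 26 with the immune score (23 shared), 7 without the 3 libraries and 846 with DESeq2 (186 shared). The average (0) became 32 with no filter, 15 with 1 surrogate variable, 6 with the mitochondrial share and 172 with DESeq2. The 78 of the joint test became 386 with no filter, 25 with the length offset, 176 with 1 surrogate variable, 5 with the immune score, 38 with the mitochondrial share, 38 without the 3 libraries, 30 with the groups compared alone, 45 with limma-voom and 1013 with DESeq2. Between 30 and 60 min (0) there were 2 without the 3 libraries and 5 with DESeq2. The 168 from 60 to 120 min became 279 with no filter, 46 with the length offset, 52 with 1 surrogate variable, 101 with the immune score, 4 with the mitochondrial share, 6 without the 3 libraries, 0 with the groups compared alone and 951 with DESeq2. The 151 from 30 to 120 min became 32 with the length offset, 277 with 1 surrogate variable, 5 with the immune score, 315 without the 3 libraries, 4 with the groups compared alone and 838 with DESeq2. Leaving out 1 library at a time gave 0 to 0 genes for sensitization, 0 to 1 at 30 min, 0 to 385 at 60 min, 7 to 240 at 120 min, 0 to 5 for the average, 0 to 356 for the joint test, 0 to 1 between 30 and 60 min, 0 to 1151 from 60 to 120 min and 4 to 67 from 30 to 120 min. All 188 genes of 120 min that a setting tested kept their sign in it, with a median absolute log2 fold change of 0.75 to 0.83, and all had an unadjusted p under 0.05 except with the length offset (181 of 188). These genes were selected by p in the same libraries and did not overlap there, so in most settings the kept signs are no separate support. The setting with PBS mice as control differs, since those controls were not in the comparison that selected the genes. There all 188 kept their sign, with a median absolute log2 fold change of 0.75, and 117 had an edgeR adjusted p under 0.05. The 120 min libraries were the same, so this check is only partly separate. Among lists called with all libraries or in the setting concerned, medians changed sign in 20 cases, each with 1 library left out. Changes of sign of lists called in neither are not counted. Each of these lists is given here with its lowest and highest median. For sensitization, the brush border list ran from −0.15 to 0.4 (−0.15 without PBS replicate 1, −0.09 without sensitized control replicate 1). The circadian list ran from −0.08 (without sensitized control replicate 1) to 0.69, and the xenobiotic list from −0.05 (without PBS replicate 1) to 0.29. The B cell list ran from −1.69 to 0.09 (0.04 without PBS replicate 1, 0.09 without sensitized control replicate 2). The goblet list, not called, ran from −0.16 to 0.45 (0.45 without PBS replicate 1, 0.13 without sensitized control replicate 1). At 30 min the interferon list ran from −0.74 to 0.05 (0.05 without sensitized control replicate 3, 0.04 without 30 min replicate 3). The stromal list ran from −0.08 (without 30 min replicate 1) to 3.11. The B cell list, not called, ran from −0.57 to 1.43 (1.43 without sensitized control replicate 3, 0.42 without 30 min replicate 2). At 60 min, without sensitized control replicate 3, the highest medians were reached by the T cell (−1.35 to 0.09), MHC class II (−0.61 to 1.26) and B cell lists (−1.03 to 0.95). The mitochondrially encoded list ran from −0.52 (without 60 min replicate 3) to 0.59. For the average, the T cell list ran from −1.04 to 0.14 (without sensitized control replicate 3). Between 30 and 60 min, the mitochondrially encoded (−0.26 to 0.84) and erythroid lists (−0.41 to 1.5) were lowest without 60 min replicate 3. Over all settings, named genes kept their side of the threshold in 2536 cases, lost it in 819 and gained it in 67, with 0 changes of sign past the threshold. List tests kept their side in 2199 cases, lost it in 251 and gained it in 120. No paired analysis was possible because the labels give the mice no numbers shared between groups. The alternative with sex as a covariate was not run, since both sexes were not present. At 15661513 to 22691349 counts per library and 3 mice per group, 3.5% of simulated 1.5-fold changes at 120 min were recovered, so a gene that did not pass is not shown to be unchanged.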

Other observations

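Counts of the haemoglobin genes, which mark red blood cells, were summed because their reads are shared. This test was chosen only after the lower erythroid list at 30 min had been seen, and its p are adjusted over the 3 times but not for that choice. The sum was at 139 ± 35.4 CPM in the 6 unchallenged mice (73.3 to 165). At 30 min it was at 34.7 ± 17.4 CPM (20.8 to 54.2), below all 6 unchallenged libraries (exact two-sided permutation p = 0.0119, the smallest that 84 permutations can give, adjusted p = 0.0357). At 60 min it was at 54.3 ± 46.4 CPM (16.4 to 106, exact permutation p = 0.0238, adjusted p = 0.0357). At 120 min it was at 83.1 ± 4.92 CPM (77.5 to 86.7, exact permutation p = 0.0833, adjusted p = 0.0833) and did not pass. The amount of blood in each isolate is not given in the sources used here.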
